A study of Mus musculus with 6 samples.

How the data were processed

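DNA methylation was measured by methylated DNA immunoprecipitation and sequencing (MeDIP-seq) in the hippocampus of 6 male C57BL/6 mice at postnatal day 21. In this assay sonicated genomic DNA is pulled down with an antibody against 5-methylcytosine and sequenced, so that stretches holding many methylated cytosines gather reads and are called as peaks. Per the labels' protocols, 3 pups received ethanol at 2.5 g/kg in 0.15 M NaCl and 3 received 0.15 M saline, by 2 subcutaneous injections on postnatal day 4 and again on postnatal day 7. Each library is labelled with the treatment of its own animal, so the 6 libraries were taken as 3 against 3 biological replicates. Per the labels the pups were littermates, but how many litters there were and which animals shared one is not given in the sources used here, so the tests treat the animals as independent. An immunoprecipitation with nonspecific IgG was done in parallel, per the labels' protocols, and was not analysed here.

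Per the labels, sequencing ran for 150 cycles, reads were aligned to the mouse genome build mm10 with Bowtie (Bowtie2 version 2.1.0 per the submitters' processing notes), and enriched regions were called with MACS version 2 at a stated q of 1e-4. The authors deposited a peak list per library, so peaks had been called in each library separately and not on pooled samples. Per the file headers, each peak carries its start, end and length, the pileup of tags at its summit (a coverage signal, not a read count scaled to depth), its fold enrichment (a linear ratio of the summit to the local background), its q and the nearest gene. The deposited column headed q holds -log10 of q, and its smallest value was between 5.00 and 5.23 in the 6 lists, so that the lists were in effect stricter than the stated threshold. The file headers also give the signed distance from summit to transcription start site (TSS) and a class of promoter, gene body or intergenic. Peaks classed as promoter had their summit within 2000 bp of the TSS of a coding RefSeq transcript. Fold enrichment and -log10 q are the authors' values, and they were used mainly to describe, rank or filter peaks within a list. Fold enrichment also entered the relative depth described below, and its median per list was compared between the groups. Bands of -log10 q were used to pick regions of similar significance.

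The deposited lists hold no library totals. A relative depth was read from the values: the summit pileup plus 1, divided by the fold enrichment, minus 1, gives the background that the ratio was set against. In each list this background had a floor, between 1.85 and 2.65 across libraries, and above it lay on steps of 0.048 for over 99.9% of peaks (tolerance 0.02 of a step). Whether a control library entered the calling is not given in the sources used here. The floor was used as a measure of relative depth only. The reference used here was GRCm38, the assembly of which mm10 is another name. Of 13798 transcripts in the lists, 13763 had a gene identifier in its RefSeq table and 97.8% of these started inside the reference gene, and on all 22 chromosomes with peaks the last peak ended within the reference length. CpG density and the share of soft-masked bases, which mark repeats, were computed from this sequence, and the feature at a summit was taken from GENCODE release M21. Coordinates are on mm10 and count from 1.

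A peak annotated to several genes is listed once per gene, and was counted once. The union of all peaks was merged to regions where peaks shared at least 1 bp, and a library was taken to hold a region if it had a peak in it. The lists used here hold no read counts for regions without a call, so presence was the only readout of single regions compared between libraries. A peak that is missing from a list shows only that the sequence did not pass the threshold there. A region was called ethanol-specific if it had a peak in 3 of 3 ethanol and 0 of 3 saline libraries, and saline-specific in the reverse case. The same rule was applied to genes with a promoter peak. Values per library were compared by two-sided exact permutation tests over all divisions of the 6 libraries into 3 and 3, which cannot give a p below 0.1. Counts of group-specific regions and genes were set against the other 9 of the 10 divisions. Benjamini-Hochberg adjustment was made within each family of tests. Shares of peaks within a library carry Wilson 95% intervals, which cover counting error only.

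Before the data were examined, 23 gene lists were fixed: imprinted genes, germline genes methylated in somatic tissue, housekeeping genes with CpG island promoters, DNA methylation machinery, histone modifiers, glutamate receptors, GABA receptors, free radical scavenging, peroxisome biogenesis, ethanol metabolism, apoptosis, neurotrophins and activity-regulated genes, stress axis, hippocampal development and neurogenesis, clustered protocadherins, Hox genes, olfactory receptors, and markers of neurons, astrocytes, the oligodendrocyte lineage, microglia, endothelium and choroid plexus. Lists with at least 3 members among genes with a promoter peak were tested for enrichment among group-specific genes by Fisher's exact test, two-sided, in both directions. The genes named in the text were chosen by a rule fixed at the same time: the 10 promoter regions per direction with the highest value of the lowest of the 3 within-list percentile ranks of q, passing over symbols that start with Gm or end with Rik, every list member with a group-specific promoter peak, the 5 genes with promoter peaks in all 6 libraries and the highest mean rank, and up to 4 members each of the imprinted, germline and housekeeping lists. Genes named outside this rule are said to be so.

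Alternatives fixed beforehand were leaving out each library, a stricter q of 1e-6, autosomes only, lists of equal length (the 18922 most significant peaks of each), a test in blocks of same-numbered libraries, other overlap, bin and merging rules, a Jaccard index in regions, promoter peaks within 1000 bp, any annotated peak, and another enrichment background. To weigh list length, the chance of each set of libraries to share a region was modelled from library weights alone, given the number of libraries holding it, by conditional maximum likelihood with 10000 multinomial draws. The functions were tested on simulated data, which checks the code only. Planted regions were present in every library of a group and in none of the other. All of 200 planted ethanol-specific and all of 100 planted saline-specific regions were recovered among 25825 simulated regions. With no treatment effect, and data simulated from a model of the same form, the model expected 488 ethanol-specific regions where 487 had been simulated. It expected 48.4 saline-specific regions where 55 had been simulated, among 25525. These simulations do not show how well the model describes the real lists. The calculations used Python 3.11 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.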

Results

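The data are 6 lists of methylated regions from the hippocampus of male C57BL/6 mice at postnatal day 21, 3 from pups injected with ethanol on postnatal days 4 and 7 and 3 from pups injected with saline. The animals are described as matched littermates, but which of them shared a litter is not given in the sources used here, and the tests treat the 6 as independent. Injection of ethanol in the first postnatal week is used to model heavy alcohol exposure of the developing brain, and the comparison asks whether DNA methylation still differed 2 weeks later. The lists held between 18922 and 34904 peaks. Background pileup, the available measure of relative depth, was 2.28 ± 0.0988 in ethanol and 2.18 ± 0.419 in saline libraries (SD, n = 3 each; exact permutation p = 0.9). The lowest background pileup, 1.85, and the highest, 2.65, were both in saline libraries.

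Methylated peaks in the juvenile hippocampus lay mostly outside genes. Between 72.3% and 73.1% of the peaks of a library were intergenic, 23.8% to 24.7% were in gene bodies and 2.87% to 3.24% were at promoters. Of 29 germline genes, which are kept silent by promoter methylation in somatic tissue, 24 had a promoter peak in at least 1 library and 16 had it in all 6, among them Asz1, Brdt, Dazl and Ddx4. Of 43 imprinted genes, whose parental alleles differ in methylation, 19 had a promoter peak and 10 had it in all 6 libraries, among them Cdkn1c, Gnas, Impact and Mcts2. Noncoding members of the imprinted list could not count here, because the promoter class refers to starts of coding transcripts. None of the 20 housekeeping genes had a promoter peak in any library.

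The promoters with the highest ranks of q in all 6 lists were those of Erdr1, Sfi1, AY761185, Zfp236 and Dazl. The Erdr1 peak (chromosome Y, 90785424 to 90786497) had a fold enrichment of 14.3 to 15.4 across the libraries, the Sfi1 peak (chromosome 11, 3192680 to 3193909) 9.73 to 10.8 and the AY761185 peak (chromosome 8, 20945818 to 20946793) 12.1 to 13.7. Zfp236, a zinc finger gene, had 13.04 to 14.3 (chromosome 18, 82693955 to 82695064). Dazl, which encodes an RNA-binding protein of germ cells, had 14.7 to 16.7 (chromosome 17, 50293197 to 50294110). These folds are the authors' and describe each list alone. The ranks do not order promoters by fold or by degree of methylation. The Sfi1 peak had a -log10 q of 857 to 961 and the Dazl peak, with the higher fold, 178 to 282. How reads matching several copies of a sequence were treated is not given in the sources used here, which limits these ranks too. Prpf18, named after its values were seen, ranked lower with a fold of 15.7 to 18.3.

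Regions found in more libraries were richer in CpG and in repeats. The 6 lists merged to 48853 regions, of which 16959 were held by a single library and 10276 by all 6. Median CpG density was 1.73 per 100 bp in regions of a single library and 3.46 per 100 bp in regions of all 6. The median share of soft-masked, repeat-derived sequence was 37.1% and 69.1% in the same sets.

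**Figure D1:**
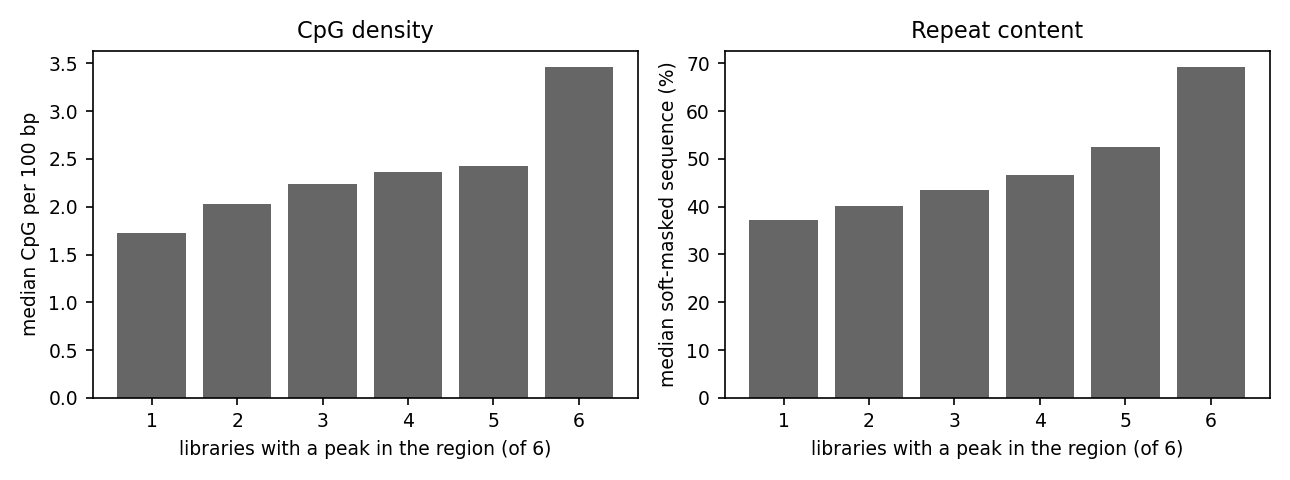
Median CpG density (left, CpG per 100 bp) and median soft-masked sequence (right, percent) of merged regions, by the number of libraries (1 to 6) holding a peak in them. CpG density was 1.73 per 100 bp in regions of a single library and 3.46 in regions of all 6, and soft-masked sequence was 37.1% and 69.1%.

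Ethanol libraries yielded more methylated peaks than saline libraries. Ethanol lists held 28810.3 ± 5893 peaks and saline lists 20800.3 ± 1891 (SD, n = 3 each), a 1.39-fold difference, and the peaks covered 18.4 ± 3.96 Mb and 13.03 ± 1.30 Mb. The shortest ethanol list, 23141 peaks, was longer than the longest saline list, 22703 peaks. Peaks with 2 to under 5 CpG per 100 bp numbered 15723 ± 3158 in ethanol and 11025 ± 429 in saline libraries, and their groups did not overlap. Peaks with under 2 CpG per 100 bp numbered 10089 ± 2911 and 6847 ± 1674, with overlapping groups (exact permutation p = 0.2). Peaks with 5 or more CpG per 100 bp numbered 2998 ± 39.4 and 2929 ± 130, and the median soft-masked share of peaks was 52.8% ± 3.95 and 59.5% ± 2.46.

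The exact permutation p was 0.1 for the number of peaks and for the covered length, the smallest that 3 against 3 libraries can give, and 0.25 after Benjamini-Hochberg adjustment over 20 measures per library. Chance separates the groups completely in 10% of measures, and 8 of the 20 did so. All of these but the median soft-masked share were counts of peaks or genes, or covered length, which rise with list length. They are thus not independent differences. The longest list, of ethanol replicate 2 with 34904 peaks, carried much of the size: without it the difference in peaks fell from 8010 to 4963 and that in covered length from 5.35 to 3.32 Mb.

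**Figure D2:**
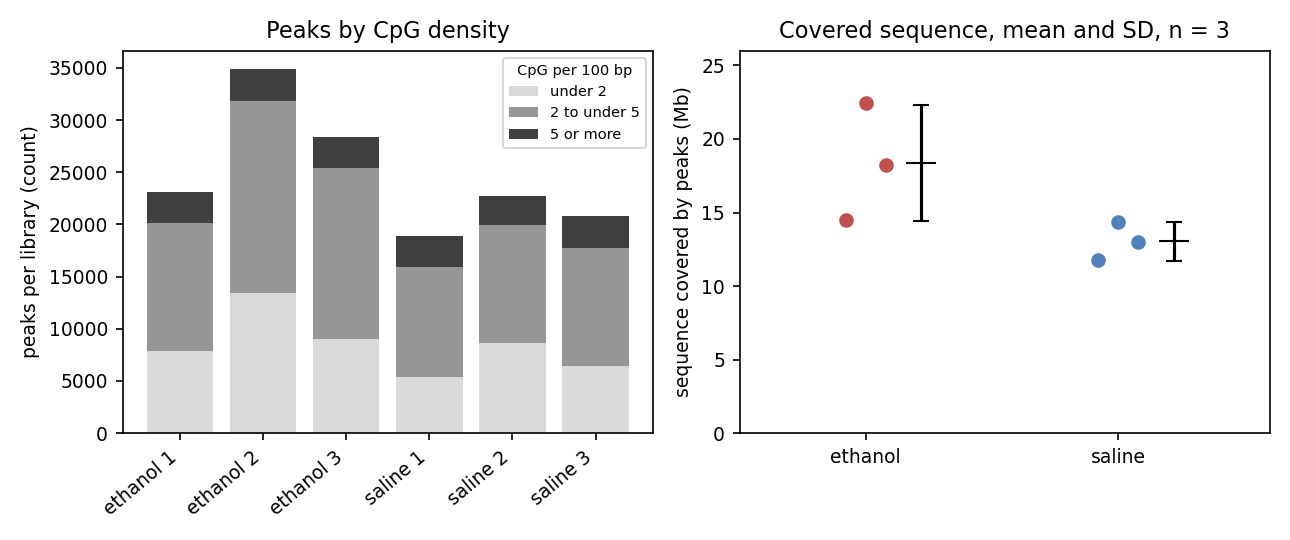
Left, peaks per library (count), stacked by CpG density of the peak; right, sequence covered by peaks (Mb), with a point per library and the mean and SD of each treatment beside them (n = 3). Ethanol libraries held 23141 to 34904 peaks and saline libraries 18922 to 22703, while peaks with 5 or more CpG per 100 bp numbered 2779 to 3043 in every library.

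The distribution of peaks over promoters, gene bodies and intergenic sequence was close in the treatments. Promoter peaks made up 3.00% ± 0.118 of ethanol and 3.14% ± 0.0892 of saline peaks (SD, n = 3; exact permutation p = 0.2). The difference of -0.136 percentage points was -0.0691 without ethanol replicate 2 and -0.0847 without saline replicate 3. The Wilson 95% intervals of single libraries spanned 2.70% to 3.49%. Gene body peaks made up 24.3% ± 0.439 and 24.1% ± 0.199 (exact permutation p = 0.6). Genes with a promoter peak numbered 860.0 ± 142 in ethanol and 653 ± 60.5 in saline libraries (exact permutation p = 0.1).

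Libraries of a treatment shared little more sequence with each other than with libraries of the other treatment. The mean Jaccard index, base pairs in both lists over base pairs in either, was 0.458 ± 0.0165 among ethanol libraries, 0.473 ± 0.0287 among saline libraries and 0.449 ± 0.0396 between treatments (SD over 3, 3 and 9 pairs, which share libraries). Ethanol replicate 1 had an index of 0.455 to 0.512 with the saline libraries and of 0.442 to 0.459 with the other ethanol libraries. The difference of the within and between means, 0.0168, was matched or exceeded by 2 of the 10 divisions of the libraries, the real one included (exact permutation p = 0.2). It ranged from 0.00391 without ethanol replicate 2 to 0.0447 without ethanol replicate 1, and was also lower, at 0.00661, without saline replicate 1. It fell to 0.00390 with lists of equal length.

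Many more regions had a peak in all ethanol and no saline libraries than the reverse. Of the 48853 regions, 727 (1.49%) had a peak in 3 of 3 ethanol and 0 of 3 saline libraries and 53 (0.108%) had the opposite pattern. Of the ethanol-specific regions 552 were intergenic, 151 lay in gene bodies and 24 at promoters; of the saline-specific regions 35, 14 and 4 did. Median CpG density was 2.63 per 100 bp in ethanol-specific and 1.37 per 100 bp in saline-specific regions, against 2.24 in all regions held by exactly 3 libraries. No single region can pass 0.05 in this design.

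These counts moved with list length. With the 18922 most significant peaks of each library, 215 regions were ethanol-specific and 191 saline-specific. Leaving out a library, which loosens the rule to 2 libraries on that side, gave 1143 (without saline replicate 1) to 2926 (without ethanol replicate 1) ethanol-specific and 111 (without ethanol replicate 3) to 267 (without saline replicate 1) saline-specific regions, and in each case the former were more numerous.

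**Figure D3:**
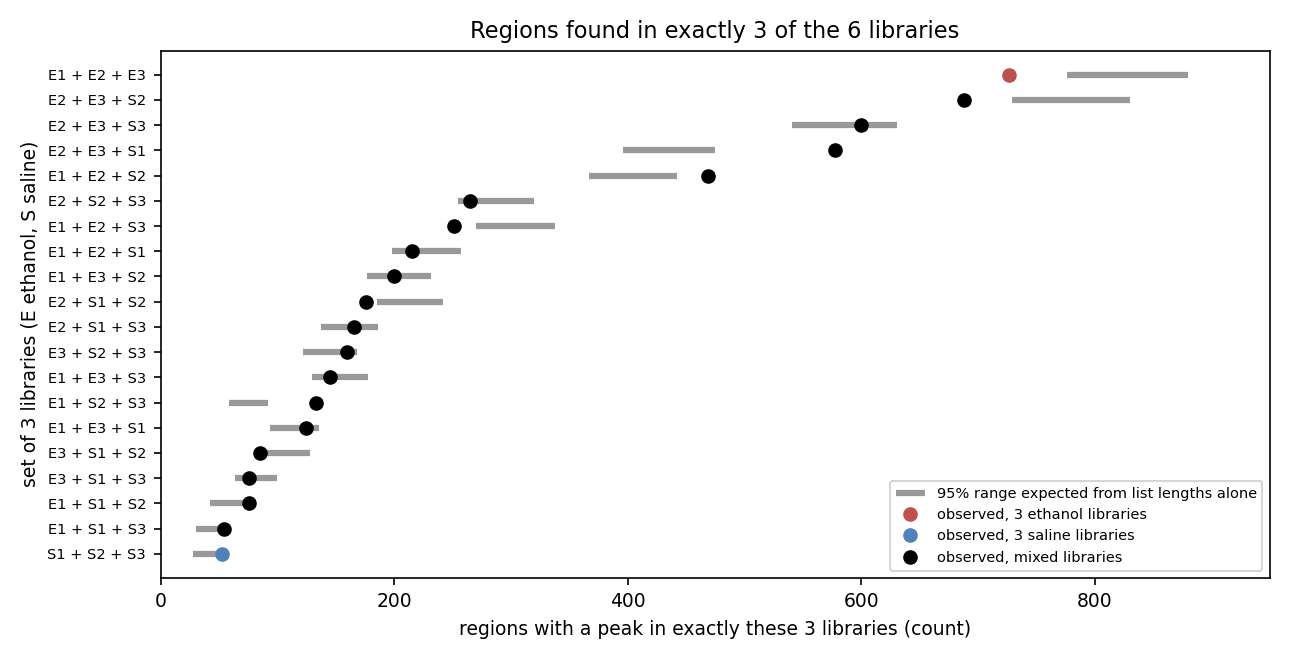
Number of regions (horizontal axis) with a peak in exactly the 3 libraries named on the vertical axis (E ethanol, S saline, with replicate number), for all 20 sets, beside the 95% range expected from list lengths alone (grey). List lengths enter this range as a weight per library, fitted to the same regions. The 3 ethanol libraries shared 727 such regions, below their range of 776 to 880, and the 3 saline libraries shared 53, just above their range of 28 to 52.

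Promoter peaks found in every ethanol and no saline library belonged to 25 genes of varied function. The highest ranked were at Sfpi1, which encodes the myeloid transcription factor PU.1, Mrgpra6, a Mas-related receptor gene, Tmem212, Pcdhb14, a clustered protocadherin, Ltf, which encodes lactoferrin, Krt25, a hair follicle keratin gene, Epb4.1l1, which encodes a cytoskeletal protein of the band 4.1 family, Slc10a1, a bile acid transporter gene, Pf4, which encodes a platelet chemokine, and Smap2. The other 15 were Alpi, BC027072, Cdc14b, Csl, Gm1140, Gm13152, Gm14692, Ifnz, Olfr503, Pold1, Snx18, Taf9b, Tcf7l1, Yy2 and Zar1l, listed here after their values were seen except for Olfr503, a member of the olfactory receptor list.

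The Sfpi1 peak (chromosome 2, 91095782 to 91096335; NM_011355) had its summit 750 to 874 bp upstream of the annotated start, in an intron of Spi1 in GENCODE, with a fold enrichment of 5.15 to 6.04 over the 3 ethanol libraries and a summit pileup of 58 to 64. The Mrgpra6 peak (chromosome 7, 47188949 to 47189613; NM_205821) lay in a coding exon with a fold of 8.99 to 9.80. The Pcdhb14 peak (chromosome 18, 37449070 to 37449704; NM_053139) lay in its coding exon, 1743 to 1814 bp downstream of the start, with a fold of 7.80 to 8.30 and 4.25 CpG per 100 bp. Krt25 (chromosome 11, 99322472 to 99323068) and Slc10a1 (chromosome 12, 80967607 to 80968237) also had the peak in a coding exon, with folds of 6.27 to 6.65 and 8.07 to 9.96. The Pf4 peak (chromosome 5, 90772491 to 90773071) was intronic, with a fold of 7.17 to 8.25. The peaks of Tmem212 (chromosome 3, 27897250 to 27897791), Ltf (chromosome 9, 111018262 to 111018797), Epb4.1l1 (chromosome 2, 156418888 to 156419454) and Smap2 (chromosome 4, 121017848 to 121018356) lay upstream of the start, where GENCODE has no gene. The Olfr503 peak (chromosome 7, 108542376 to 108542958) was 1858 to 1950 bp upstream of its start.

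With lists of equal length, 7 genes were ethanol-specific by promoter peak, and all 7 were among the 25: Csl, Gm13152, Krt25, Mrgpra6, Olfr503, Sfpi1 and Tmem212. Leaving out a library gave 35 (without saline replicate 1) to 66 (without ethanol replicate 1) genes, and promoter peaks within 1000 bp of the start gave 15. At q of 1e-15 or less, a threshold chosen after seeing the data, 23 genes were ethanol-specific, of which 15 were among the 25 and 8 were not.

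Promoter peaks found in every saline and no ethanol library belonged to 5 genes: Snrpn and Snurf, which are imprinted and share a promoter, Sema3f, which encodes a secreted axon guidance protein, Rhox4e, a reproductive homeobox gene on the X chromosome, and I830012O16Rik. The Snrpn and Snurf peak (chromosome 7, 60003935 to 60004678; NM_013670 and NM_033174) had its summit 888 to 914 bp downstream of the start, in the intron after the first exon. It had a fold of 8.30, 8.10 and 7.48, a -log10 q of 17.6, 19.4 and 13.9 and a summit pileup of 28, 32 and 23 in saline replicates 1, 2 and 3. The nearest ethanol peak was 42579 bp away, in a region downstream of Snrpn that had a peak in all 6 libraries. The Sema3f peak (chromosome 9, 107710691 to 107711352; NM_011349) lay 446 to 672 bp upstream of the start, where GENCODE has no gene, with a fold of 6.63 to 8.07 and 0.604 CpG per 100 bp. The Rhox4e peak (chromosome X, 37557240 to 37557838; NM_201236) lay in an untranslated exon with a fold of 8.01 to 10.0.

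All 5 saline-specific genes were also saline-specific with lists of equal length, where the count was 9. The Snrpn peak ranked low in its lists, at percentile 13.1 in the lowest of the 3. At q of 1e-15 or less, 3 genes were saline-specific: Rhox4e and I830012O16Rik, which were among the 5, and Zbtbd6, which was not and is named after its values were seen. Leaving out a library gave 6 (without ethanol replicate 3) to 11 (without saline replicate 1) genes. Rhox4e, Olfr503, Pcdhb14 and Mrgpra6 belong to families of similar genes in clusters, and how reads matching several copies were treated is not given in the sources used here.

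**Figure D4:**
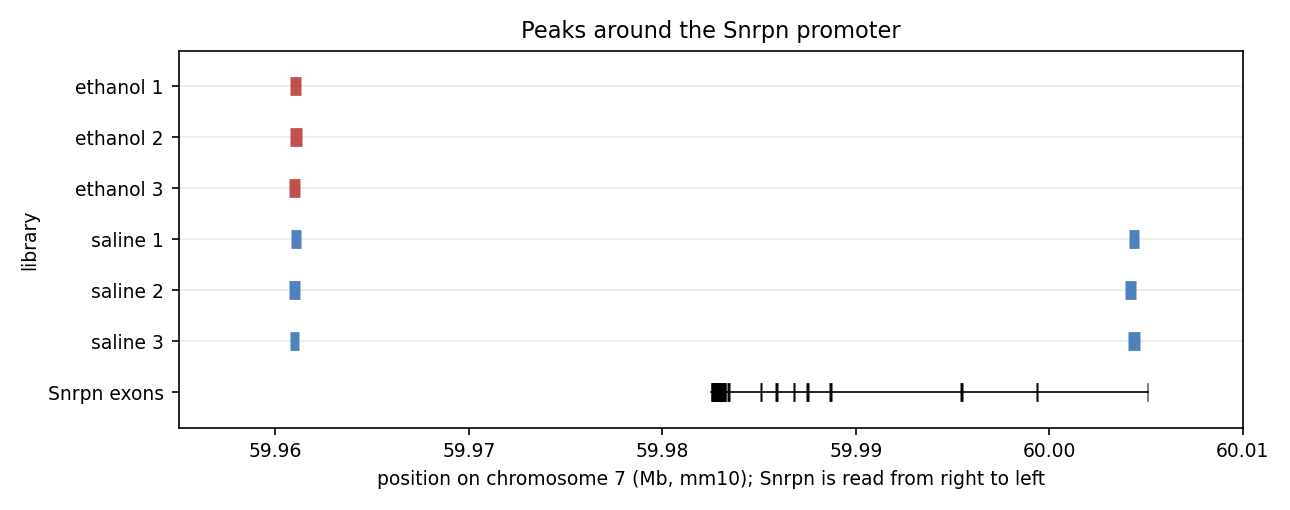
Peaks of the 6 libraries (rows; red ethanol, blue saline) around Snrpn on chromosome 7 (horizontal axis, Mb, mm10), with the Snrpn exons of GENCODE in black; the gene is read from right to left. The 3 saline libraries had a peak at 60003935 to 60004678 near the first exon, where no ethanol library had one, and all 6 libraries had a peak near the left edge.

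Only the imprinted, germline, clustered protocadherin and olfactory receptor lists had enough members with a promoter peak to be tested for group-specific promoters. Of these, imprinted genes were the only list past the test, and that call rested on a single peak. Of 19 imprinted genes with a promoter peak, 2 were among the 5 saline-specific genes where 0.0648 were expected from 1466 genes (Fisher's exact test, adjusted p = 0.0124 over 8 tests). The 2 are Snrpn and Snurf, annotated to the same peak. Fisher's test takes genes as its units, so its p does not measure variation between animals. With symbols that share their promoter peaks counted once, a setting chosen after seeing the data, the adjusted p of the exact test was 0.391, and over all settings that could test the list it ranged from 0.00183 to 1. It was 0.0678 without saline replicate 1, 0.0573 without saline replicate 3 and 0.0617 with lists of equal length. Of 40 clustered protocadherins and 60 olfactory receptors with a promoter peak, only Pcdhb14 and only Olfr503 were ethanol-specific, and none of the 24 germline genes was group-specific (adjusted p = 1 in each exact test).

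Olfactory receptor genes, which are expressed in the nose, had promoter peaks at 39.7 ± 6.81 members in ethanol and 27.3 ± 3.79 in saline libraries (SD, n = 3; exact permutation p = 0.1, 0.543 adjusted over 38 tests). Clustered protocadherins, cell adhesion genes that mark individual neurons, had 31.7 ± 1.53 and 28.3 ± 1.53 members with one (exact permutation p = 0.2). Germline genes had 21.3 ± 1.53 and 19.7 ± 1.15, and imprinted genes 13.3 ± 1.15 and 15 ± 1 (exact permutation p = 0.3 for each). As a share of all genes with a promoter peak, olfactory receptors made up 4.62% in ethanol and 4.17% in saline libraries, while protocadherins (3.75% and 4.36%) and germline genes (2.54% and 3.02%) went the other way from their counts (exact permutation p = 0.3 for each of the 3 lists). Imprinted genes made up 1.57% and 2.30% (exact permutation p = 0.1), and without Snrpn and Snurf, left out after seeing the data, 1.57% and 1.99% (exact permutation p = 0.1 again), with counts of 13.3 ± 1.15 and 13 ± 1 (exact permutation p = 1). All these shares are of a larger number in ethanol libraries, 860.0 genes against 653. Peg3 and Usp29, which share a promoter on opposite strands, show how annotation enters such counts: Peg3 had a promoter peak in 1 ethanol and 3 saline libraries and Usp29 in 2 and 0, yet these were peaks of the same region (chromosome 7, 6729376 to 6731143), held by all 6 libraries, whose summits differed by 412 bp.

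**Figure D5:**
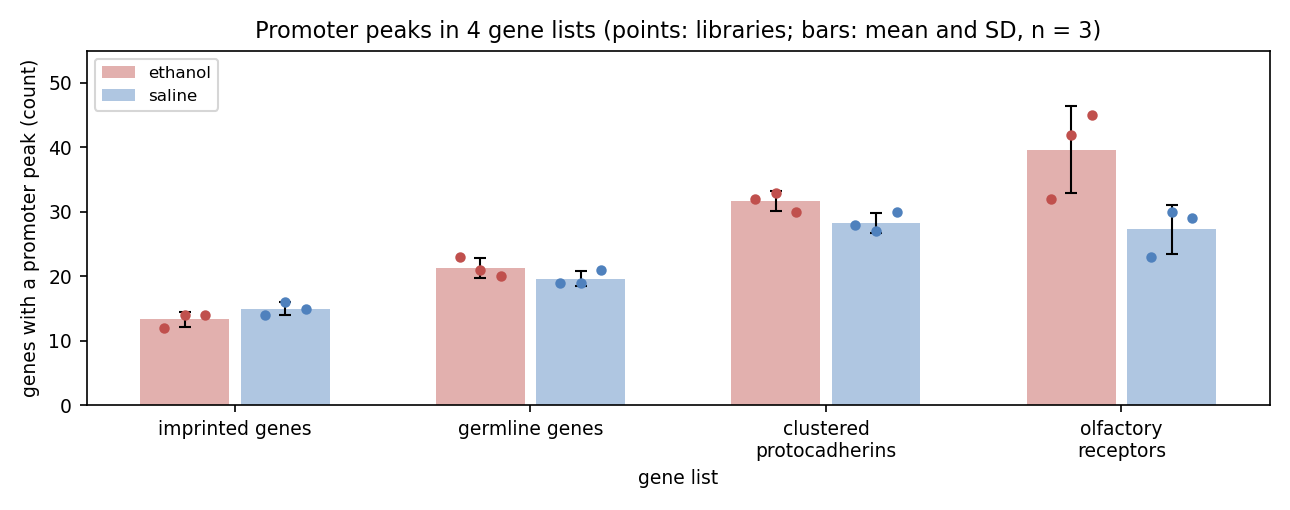
Number of genes with a promoter peak (vertical axis, count) in 4 gene lists, with a point per library and bars for the mean and SD of ethanol (red) and saline (blue) libraries (n = 3). Olfactory receptors had means of 39.7 in ethanol and 27.3 in saline libraries, and imprinted genes 13.3 and 15; the counts are not scaled to the number of genes with a promoter peak.

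Hippocampal development and neurogenesis genes, free radical scavenging genes, peroxisome biogenesis genes, Hox genes and markers of neurons, microglia and choroid plexus had no promoter peak in any library. In at least 1 library there was a promoter peak at 1 member of the DNA methylation machinery (Dnmt1), 1 histone modifier (Hdac7), 2 glutamate receptors (Grin1 and Grm4), 1 GABA receptor (Gabrb2), 2 ethanol metabolism genes (Adh4 and Adh7), 2 apoptosis genes (Casp6 and Casp8), 2 neurotrophin or activity-regulated genes, 2 stress axis genes (Avp and Crhbp), 1 astrocyte marker (Aldh1l1), 2 oligodendrocyte lineage markers (Cspg4 and Mobp) and 2 endothelial markers (Cldn5 and Pecam1), named after their values were seen. Of the apoptosis genes, Casp6 had a promoter peak in 1 ethanol library and Casp8 in the other 2, so that no gene had it in all 3, and no saline library had any (exact permutation p = 0.1, 0.543 adjusted over 38 tests). Counting any annotated peak, 22 of the 23 lists had a higher mean number of members in ethanol libraries, but as a share of all genes with a peak 9 had. At least 1 peak was annotated to 25 of the 26 glutamate receptors and to 29 of the 30 hippocampal development genes. Peaks were annotated to the nearest gene, which can lie far away, and 13142 genes had such a peak in at least 1 library. Whether these lists exceed other genes in this was not tested.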

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

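The settings with q of 1e-15 or less, background pileup, GENCODE transcript starts, shared symbols counted once, and no peak of the other treatment within 1000 bp were chosen after seeing the data. The differences in peaks, covered length, promoter share and similarity kept their direction in all 11, 10, 12 and 11 settings tried for them, though none can pass 0.05 with 3 against 3 libraries. Without each library in turn they ranged from 4963 to 10845 peaks, from 3.32 to 7.28 Mb, from -0.179 to -0.0691 percentage points and from 0.00391 to 0.0447. In blocks of same-numbered libraries, the differences were again 8010 peaks, 5.35 Mb and -0.136 percentage points, with a sign-flip p of 0.25, the smallest possible. Deviations of same-numbered libraries correlated at -0.0496, -0.0117 and 0.00249, and no ethanol library correlated best with its own number. Values this small can neither show nor exclude pairing. The sources used here do not say that the numbers pair the animals, and they were not taken to do so. Counts of group-specific regions stayed within 1.5 times in 6 of 14 settings per direction. Without each library they ranged from 1143 to 2926 for ethanol and from 111 to 267 for saline, where the looser rule itself raises the count. Lists of equal length gave 215 and 191 regions, and 1000 bp bins 424 and 26. Ethanol-specific and saline-specific promoter genes numbered 35 to 66 and 6 to 11 without each library, 7 and 9 with lists of equal length, and 174 and 9 by any annotated peak. They numbered 113 and 11 by GENCODE starts, which add noncoding genes and further starts of coding genes. Summits within 1000 bp gave 15 ethanol-specific genes, a narrower window, and q of 1e-15 or less 3 saline-specific genes. The number of gene lists past 0.05 was 0 to 1 without each library, and 0 with lists of equal length, with q of 1e-15 or less and with shared symbols counted once. Against a background of genes in exactly 3 libraries the imprinted list had 2 members, fewer than the 3 required, and gave no value. The causes of the changes with 1000 bp bins and with GENCODE starts were not tested. Depth limits these results in that a missing peak cannot be told from one just below the threshold.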

Other observations

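Of the members of the gene lists, 3 had an ethanol-specific and 1 a saline-specific region in the gene body, named here after their values were seen. Ethanol-specific gene body regions lay in Apaf1, a core gene of the mitochondrial cell death pathway (chromosome 10, 90995391 to 90995987, fold 8.72 to 8.97), in Kdm4a, a histone demethylase gene (chromosome 4, 118162317 to 118162815, fold 6.90 to 7.18), and in Dlk1, an imprinted gene (chromosome 12, 109462802 to 109463324, fold 6.60 to 7.45). A saline-specific gene body region lay in Gabrg3, a GABA receptor gene (chromosome 7, 57139483 to 57140078, fold 6.39 to 8.38), in sequence that was 100% soft-masked. A further 33 ethanol-specific and 2 saline-specific regions were intergenic with a list member as the nearest gene, 31 members and 2 members in all, among them 12 olfactory receptors on the ethanol side; whether this exceeds chance was not tested. By GENCODE transcript starts, which include noncoding genes, the imprinted noncoding genes Kcnq1ot1 and Peg13 had a promoter peak in all 3 ethanol and all 3 saline libraries, Meg3 in 3 and 1, Nespas in 3 and 2 and H19 in 2 and 1. By the same starts, the coding members Blcap and Sgce had one in 3 and 3 and Commd1 in 3 and 1. The promoter class of the lists gave these coding members none.

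All tests of explanations below were chosen after the results were seen. The first pattern is the longer ethanol peak lists, 1.39-fold in mean. Depth, as read from the background pileup, leaves a 1.30-fold difference in peaks per unit of background with the groups still apart, but with 3 against 3 libraries this cannot be told apart from a depth effect that is not proportional. Of the excess in mean peaks, 0.866% had 5 or more CpG per 100 bp, 58.7% had 2 to under 5 and 40.5% had under 2, so a higher sensitivity for CpG-poorer sequence in the ethanol libraries stays open. The excess was not confined to peaks near the threshold, since at q of 1e-15 or less the difference was 6542 of the 8010 peaks, and the median fold of a list was 7.49 ± 0.107 in ethanol and 7.54 ± 0.278 in saline libraries. A gain of methylation after ethanol in such sequence would look the same, and ethanol stays open as an explanation, untested, because regions without a call carry no values in these lists.

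The second pattern is the excess of ethanol-specific over saline-specific regions, 727 against 53. The model of list length gives each library a weight, fitted to these same regions, and assumes no treatment effect on single regions. It expected 826 ethanol-specific regions (95% range 776 to 880), more than observed, and 39.7 saline-specific regions (28 to 52), slightly fewer than observed. A difference in list length could thus account for the excess of ethanol-specific regions, though it does not say why the lists differ in length. An effect of ethanol on many regions would also raise the weights of the ethanol libraries, so the model cannot tell such an effect from list length. The model also fitted loosely, since 8 of the 18 mixed sets of 3 libraries fell outside their range. The mixed sets were at 0.788 to 1.77 times the expected number, and ethanol replicate 1 with saline replicates 2 and 3 had the highest ratio. For the saline-specific regions list length therefore stays open. With only 10 divisions no share under 0.05 is possible: 1 of 10, the real one, gave 727 regions or more (highest other 688) and 1 of 10 gave 25 promoter genes or more (highest other 24), while in the part with fewer, all 10 gave the 53 regions of the saline libraries or more (highest other 166) and 3 of 10 gave their 5 genes or more (highest other 8), and with lists of equal length 5 of 10 gave a total of 406 or more (highest other 596).

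The third pattern is the Snrpn promoter peak in saline libraries alone, which is of interest because this sequence lies beside the first exon of an imprinted gene and because the ethanol lists were the longer ones. A poorer capture of methylated promoters in the ethanol libraries stays open. On average 1.67 more germline genes had a promoter peak in ethanol than in saline libraries (pooled SD 1.35). Their share of all genes with a promoter peak went the other way, 2.54% in ethanol and 3.02% in saline libraries (exact permutation p = 0.3). Of the 13 imprinted promoter regions held by all saline libraries, 12 were also held by all ethanol libraries. The counts go against a general loss, but the germline share does not. The germline counts of the groups also overlapped and 16 of the 24 genes had a peak in all 6 libraries. The Snrpn region had 3.09 CpG per 100 bp. Peaks with 2 to under 5 CpG per 100 bp numbered 12273 to 18469 in ethanol and 10530 to 11295 in saline libraries. These counts rise with list length and cover all peaks, not promoters alone. They do not decide whether capture was poorer at this CpG density. Chance loss of a peak also stays open, because its probability depends on the rate taken from regions held by 3 of 3 saline libraries: the chance of losing at least 1 of 13 imprinted promoter regions is 0.0627 with each at the rate of regions within 10% of its own lowest -log10 q, 0.156 with all at the rate of regions within 10% of the Snrpn peak (15 of 1155, 1.30%) and 0.0433 with all at the rate of regions at least as significant as it (35 of 10301, 0.340%). These rates come from the same division of the libraries, and include the Snrpn region itself and any region lost after ethanol. The calculation treats the 13 regions as independent and ignores that Snrpn was picked because its peak was saline-specific. It thus does not measure chance loss alone and cannot decide the question. A loss of methylation at Snrpn after ethanol is a hypothesis that these lists neither exclude nor establish. Targeted bisulfite sequencing of this region would test it.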
